A study of Homo sapiens with 8 samples.

How the data were processed

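H3K27ac ChIP-seq peak lists of 3 MCF7 samples were analysed, 1 per treatment, all treated for 7 days. Groups were taken from the sample titles. Reads were aligned with BWA and peaks called with MACS2 on hg19, per the submitters' processing notes. Versions, options, duplicate handling and any input control are not given in the sources used here. Per the labels' protocols, crosslinked chromatin was sonicated on either of 2 Covaris instruments and libraries were made with either of 2 kits, without saying which was used for which sample.

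Each deposited list held 1 row per peak, called per sample and not on pooled samples. The deposited fold is the ratio of the pileup at the summit to the local background of the peak caller. The deposited −log10 p and −log10 q refer to the same position, and the lowest −log10 q in the lists, 1.33 to 1.35, corresponds to a q-value threshold of 0.05. The deposited score is the −log10 q in whole steps and was not used. Fold, −log10 p and −log10 q are the authors' values. They served to describe, rank and filter peaks within 1 list and to recover tag counts, and the fold also to give a median ratio at matched summits beside that of tags per depth.

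Tag counts were recovered from the lists after the data had been seen. For each peak the whole summit pileup and the background were solved so that pileup plus 1 over background plus 1 equals the fold and the Poisson tail equals the deposited −log10 p. A solution within 0.001 of the deposited −log10 p was found for 100% of the DMSO peaks and for all but 1 peak in each of the treated lists. The background was a whole number of tags per 10 kb window, within 0.02 tags, for 99.2%, 98.2% and 98.6% of peaks under DMSO, abemaciclib and the combination. Nearly all others sat at 1 lowest value per library, with 1 peak in each treated list at neither. Here the fragment length was taken as the shortest peak width, 268, 265 and 261 bp. This pattern is that of a background taken from the ChIP library itself, without an input control, with the lowest value as the genome-wide mean. Dividing that value by the fragment length gave the depth in tags per Mb of effective genome: 2246, 1465 and 2235. On simulated peaks, 3000 per library, the known pileup was recovered for 99.9% or more in each library, and a background that was no whole number of tags passed as whole in 5.17%, 3.77% and 4.30%.

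Peaks were called shared when they overlapped by at least 1 bp (bedtools 2.31.1), and otherwise gained or lost. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, since neither peaks nor tags are replicates. Clusters joined peaks at most 12.5 kb apart. Covered length was summed in fixed windows of 100 kb. Summits at most 200 bp apart that were each other's nearest were matched, and the ratio of their tags was divided by the ratio of depths. Its interval is the exact 95% interval of the binomial share of tags, and the number of summits beyond it was compared with 100 draws with the median ratio at every summit. For overlaps against the shared DMSO library, 20 sets of 3 libraries were drawn at the rates of the merged regions. Each rate was the mean over the libraries that listed the region. Draws were made either without any effect or with 1 factor per library. The threshold on −log10 p, 8.98, was set so that the DMSO list had its real length. A first draw at the lowest deposited −log10 p listed too many DMSO regions and was replaced. Scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

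The design, the alternatives and the rule for named items were fixed before the data were examined. That rule took, per comparison, the genes of the 8 promoter and 8 distal gained peaks and of the 4 and 4 lost peaks with the highest −log10 p, the 6 genes with the largest gain and the 4 with the largest loss in covered length, members of the fixed lists, and a set of check genes. Without an annotation of hg19 it could not be followed. In its place, after the data had been seen, the 16 gained and 8 lost peaks with the highest −log10 p and the 6 and 4 windows of 100 kb were ranked, and the regions printed were picked from these ranks. Clusters, windows and distances between peaks were likewise added at that stage. For matched summits with at least 100 tags over both libraries, the 5 highest and 5 lowest per comparison were ranked, a rule added later. The planned promoter shares, 20 gene lists, cell type markers and 20 sequence motifs were not run for the same reason. Alternatives were stricter thresholds, equal list lengths, other overlap rules, merged peaks and chromosome filters, and, added later, thinning to equal depth, leaving out regions of high background, fold enrichment in place of tags per depth and clusters at equal list length.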

Results

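Genome-wide H3K27 acetylation was profiled by ChIP-seq in MCF7, an established breast carcinoma cell line that expresses the estrogen receptor. H3K27ac is an acetylated form of histone H3 found at active promoters and enhancers. The cells were treated for 7 days with the vehicle DMSO, with abemaciclib, or with abemaciclib together with fulvestrant. Abemaciclib inhibits the cell cycle kinases CDK4 and CDK6 and was used at 500 nM. Fulvestrant binds the estrogen receptor and leads to its degradation, and was used at 100 nM. Peak lists of 3 samples, all from the experiment labelled Exp3, were analysed, with 1 sample per treatment. The other 5 samples of the series were not analysed here. They are MCF7 under DMSO, abemaciclib and palbociclib outside Exp3, and the breast line MDA-MB-453 under DMSO and abemaciclib. How the other MCF7 samples relate to Exp3 is not given in the sources used here. With 1 library per treatment analysed, no difference could be set against the spread between cultures, so no test between treatments was run and no p-value between treatments is given. The intervals of shares and of tag ratios at single summits below cover counting error only. Intervals of medians and of spreads come from resampled regions and do not cover the spread between cultures. Regions are given by their position in hg19, because no gene annotation or sequence of that build was used here.

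Both treated libraries had more H3K27ac peaks than the DMSO library. The DMSO list held 11675 peaks, the abemaciclib list 18542 and the combination list 19814, which is 1.59 and 1.70 times the DMSO number. Peaks covered 7.12 Mb under DMSO, 12.2 Mb under abemaciclib and 12.9 Mb under the combination. Median peak width differed little, at 541 bp, 572 bp and 556 bp in the same order. The authors' fold enrichment at the summit had a median of 6.67 in the DMSO list, 6.84 in the abemaciclib list and 6.70 in the combination list. The background that the peak caller used corresponded to 2246 tags per Mb of effective genome under DMSO, 1465 under abemaciclib and 2235 under the combination. The abemaciclib library therefore held 0.652 times the depth of the DMSO library and the combination library 0.995 times.

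**Figure D1:**
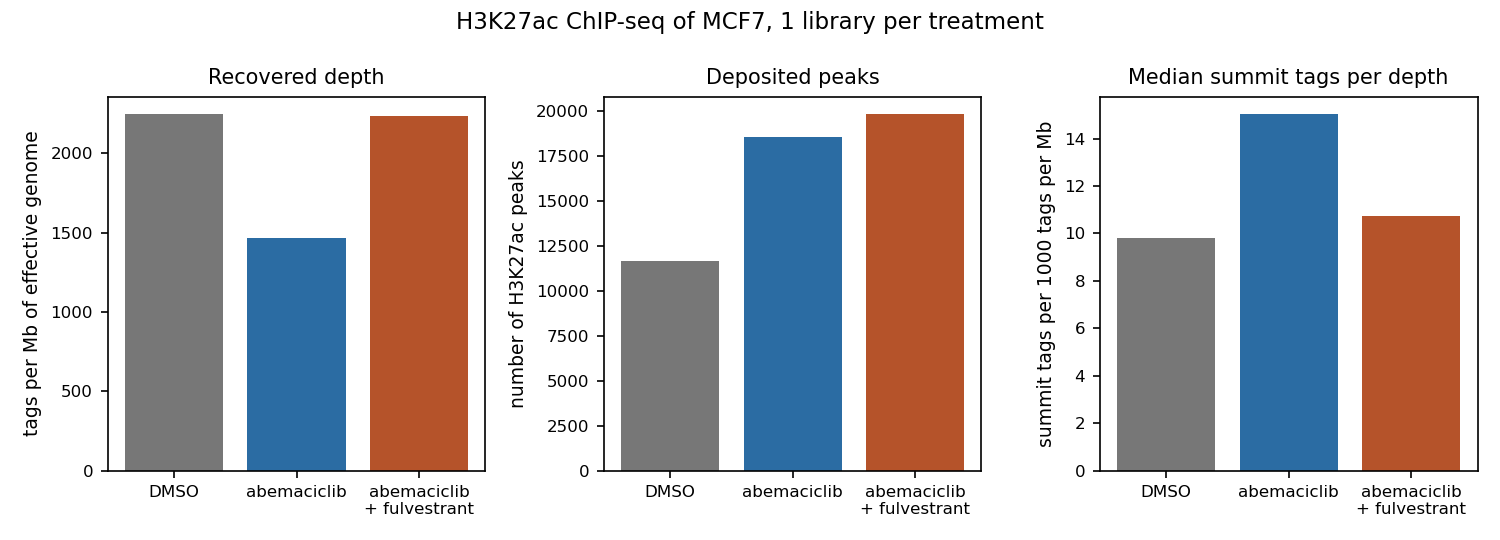
Bars give, for the single library of each treatment, the recovered depth in tags per Mb of effective genome, the number of deposited H3K27ac peaks, and the median summit pileup divided by depth. The abemaciclib library has the lowest depth, 1465 tags per Mb, and still lists 18542 peaks against 11675 under DMSO.

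The first comparison asked how the acetylated regions of MCF7 differed after CDK4/6 inhibition. Of the 18542 abemaciclib peaks, 7961 overlapped no DMSO peak and were counted as gained, or 42.9% (exact 95% interval 42.2 to 43.7%). Of the 11675 DMSO peaks, 625 overlapped no abemaciclib peak and were counted as lost, or 5.35% (4.95 to 5.78%). Gained peaks were weaker than shared peaks, with a median fold enrichment of 5.31 against 8.74 and a median of 11 against 37 tags at the summit. Lost peaks were concentrated at the bottom of the DMSO list, where the weakest 20% of peaks held 72.2% of them. Among the 5000 DMSO peaks with the highest −log10 p, 3 had no overlap in the abemaciclib list. Conversely, 43 of the top 5000 abemaciclib peaks had none in the DMSO list. When each list was shortened to its 11675 strongest peaks, 2102 peaks were gained and 1555 lost.

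Distances from gained peaks to the nearest listed DMSO peak varied widely. Their median was 33865 bp, and 24.0% (23.1 to 24.9%) of gained peaks were over 100 kb away. No distance for randomly placed positions was computed, so these values do not show whether gained peaks lay unusually far from DMSO peaks. Absence from the DMSO list is also not absence of acetylation, since weaker signal may have stayed below its threshold. The gained peak with the highest −log10 p lay on chromosome 20 at 49407106 to 49407840, with 5.31-fold enrichment and 144 tags at the summit. It lay in a stretch of high background, with 992 tags in 10 kb against a median of 84 over the abemaciclib list. The second lay on chromosome 3 at 197380898 to 197381370, with 17.7-fold enrichment and 50 summit tags, and was 82136 bp from the nearest DMSO peak. Next came chromosome 17 at 73760764 to 73761438 with 13.6-fold enrichment, and chromosome 15 at 75074445 to 75075053 with 12.1-fold. A peak on chromosome 7 at 20369545 to 20370723 was the most isolated of the 16 strongest gained peaks, 620804 bp from any DMSO peak, with 11.6-fold enrichment. All of these 16 were also listed in the combination library, as were all but 6 of the top 5000 abemaciclib peaks.

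The strongest lost peak was on chromosome 2 at 174219160 to 174220000, with 36 summit tags under DMSO, and it was missing from both treated lists. Chromosome 21 at 32114501 to 32114972 followed with 11.7-fold enrichment and 21 tags. Of the 8 strongest lost peaks, 5 lay under 500 bp from an abemaciclib peak, so that acetylation was still listed beside them. Over windows of 100 kb, the largest gain in covered length was on chromosome 7 between 100800001 and 100900000, where 6 peaks covering 5.31 kb were listed under abemaciclib and none under DMSO. The window from 55800001 to 55900000 on chromosome 20 held 5.78 kb against 1.16 kb. The 3 largest losses all fell on chromosome 17. From 59600001 to 59700000 covered length was 2.61 kb under DMSO and 1.18 kb under abemaciclib. From 59800001 to 59900000 it was 1.38 kb and from 58300001 to 58400000 it was 1.22 kb under DMSO, with no abemaciclib peak in either window. In the windows from 59600001 and 59800001, the strongest peak of the lost DMSO cluster had a fold of 3.41 and 3.45. The median over the DMSO list was 6.67. Local background in these windows was not compared between the libraries.

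Clusters of peaks followed the length of the lists. Joining peaks at most 12.5 kb apart gave 23 clusters of 5 or more peaks under DMSO, 107 under abemaciclib and 158 under the combination, which held 1.14%, 3.41% and 4.62% of the peaks. In the abemaciclib list, 83 of 855 clusters of at least 3 peaks contained no DMSO peak, against 2 of 307 DMSO clusters without an abemaciclib peak. With the 11675 strongest peaks of each list, clusters of 5 or more numbered 23, 30 and 27 under DMSO, abemaciclib and the combination, and 4 of 273 abemaciclib clusters held no DMSO peak, against 4 of 307 the other way. In the full lists, 2 of the new clusters held 5 peaks, on chromosome 20 from 46154358 to 46175694 and on chromosome 4 from 2395420 to 2420452. The DMSO cluster with the most peaks, 9, was on chromosome 6 from 26188891 to 26234513. This stretch held 12 peaks under abemaciclib and 5 under the combination.

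Tag counts recovered from the lists gave a quantitative comparison at the peaks listed in both libraries, a readout added after the data had been seen. The counts are inferred from the authors' fold and −log10 p, and the comparison leaves out every region that was listed in 1 library alone. At 9089 matched summits, tags per depth under abemaciclib were a median of 2.39 times those under DMSO, with quartiles of 1.94 and 2.94. The ratio was above 1 at 9006 of them and below 1 at 83. Medians of single chromosomes, the autosomes and X, ran from 1.18 to 1.32 on the log2 scale, where the overall median was 1.26. Tags counted in 10 kb around the summit gave a median of 2.14-fold. The authors' fold enrichment, which is taken over that local background and not per depth, had a median ratio of 1.205 at these summits. Relative to the common median, 433 summits were higher and 378 lower than their counting intervals allowed, where draws with 1 ratio for all gave 163 and 167 on average. The highest ratio among summits with at least 100 tags was on chromosome 9 at 129484440 to 129485508, with 86 abemaciclib and 19 DMSO tags, or 6.94-fold per depth (4.19 to 12.1). Chromosome 16 at 90085169 to 90086523 was 6.79-fold (4.48 to 10.6). At the other end stood chromosome 20 at 46093361 to 46094323, with 57 against 107 tags, or 0.817-fold (0.582 to 1.14).

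**Figure D2:**
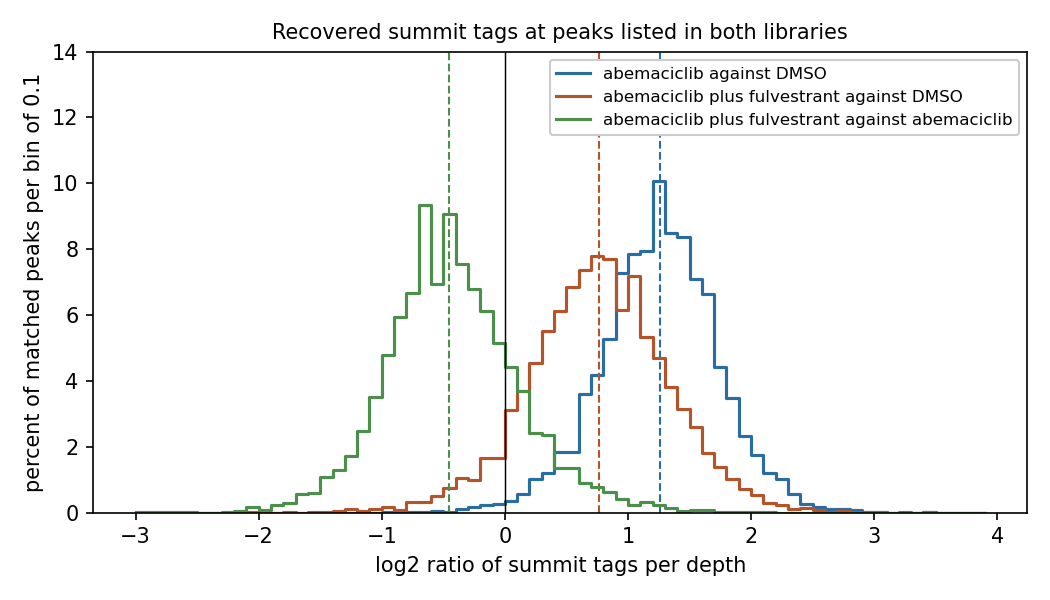
Each line is the distribution over matched peaks of the log2 ratio of summit tags per depth for 1 pair of libraries, in bins of 0.1, with its median as a dashed line. The distributions centre at 1.26 for abemaciclib against DMSO, 0.76 for the combination against DMSO and -0.46 for the combination against abemaciclib.

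The second comparison set abemaciclib plus fulvestrant against DMSO. Of the 19814 combination peaks, 9385 were gained, or 47.4% (46.7 to 48.1%), and 737 DMSO peaks were lost, or 6.31% (5.88 to 6.77%). Lists of equal length gave 2611 gained and 2021 lost. Of the top 5000 combination peaks, 177 had no overlap under DMSO, and of the top 5000 DMSO peaks, 20 had none under the combination. The gained peaks with the highest −log10 p were on chromosome 20 at 52389190 to 52390136 and at 52308414 to 52309070, with 222 and 180 summit tags. Their background was 1763 and 1204 tags in 10 kb against a median of 100 over the combination list. Chromosome 11 at 46384445 to 46385453 was next, with 12.5-fold enrichment and 93 tags. Chromosome 20 at 49407076 to 49407871 followed with 4.65-fold enrichment and 1627 tags in 10 kb. Ranks 5 and 7 were chromosome 1 at 116853967 to 116854599 with 10.5-fold and chromosome 10 at 13141839 to 13142686 with 13.8-fold. Of the 16 strongest gained peaks, 5 lay on chromosome 20. All 16 were also listed under abemaciclib alone, as were all but 15 of the top 5000 combination peaks. Lost peaks included chromosome 1 at 23856916 to 23857744 with 46 DMSO tags, 140 bp from a combination peak, and chromosome 11 at 77971435 to 77971913 with 33 DMSO tags, 74426 bp from the nearest one. The window with the largest gain in covered length was on chromosome 20 from 52400001 to 52500000, with 8.07 kb against 1.67 kb. In the combination list, 167 of 1022 clusters of at least 3 peaks contained no DMSO peak, and the longest run of these was 7 peaks on chromosome 10 from 71185997 to 71218719.

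At 8939 summits matched with DMSO, tags per depth under the combination had a median ratio of 1.70, with quartiles of 1.33 and 2.18, and were higher at 8234 summits. The median ratio of the authors' fold enrichment was 1.19. Summits above and below the counting intervals around the median numbered 756 and 685, where draws with 1 ratio for all gave 161 and 168 on average. Among summits with at least 100 tags over both libraries, the highest ratio was on chromosome X at 140227639 to 140228242, with 96 against 9 tags, or 10.7-fold (5.42 to 24.2). Chromosome 20 at 50361249 to 50361959 had 193 against 21 tags, or 9.24-fold (5.88 to 15.3). The lowest ratio among these was on chromosome 8 at 129439853 to 129440484, with 28 against 75 tags, or 0.375-fold (0.234 to 0.586), and chromosome 20 at 361462 to 362360 stood at 0.526-fold (0.358 to 0.763).

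Regions gained or lost were also counted for both treatments together. Merging the 3 lists gave 23285 regions, of which 10011 were listed in every library. Gained regions numbered 7558 under abemaciclib and 9065 under the combination, and 4219 were gained in both. Drawn on average, this number was 464 without any effect and 3862 with 1 factor per library at every region. No value for independent lists is given for gains, because regions that could have been gained but are in no list are not known. Lost regions numbered 579 and 673 with 382 in common. Independent lists among the 10881 DMSO regions would share 35.8, and the draws gave 1930 without any effect and 326 with 1 factor per library. Draws without any effect listed 7636 abemaciclib and 10866 combination regions where 17860 and 19273 were seen. Draws with 1 factor per library listed 15907 and 16407. In both kinds of draw, rates at regions absent from the DMSO list came from the treated libraries alone. The overlaps of neither kind are therefore a baseline for the real lists. Both comparisons used the same DMSO library, which could not be split, so part of these overlaps may come from that library.

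The last comparison asked what differed when fulvestrant was given with abemaciclib. The combination list held 5075 peaks with no overlap under abemaciclib alone, or 25.6% (25.01 to 26.23%), and 3661 abemaciclib peaks had none under the combination, or 19.7% (19.2 to 20.3%). With equal lengths the numbers were 1951 and 1844. The combination library was the deeper one. Over merged regions, draws without any effect gave 4218 gained regions where 5043 were seen, and 987 lost where 3630 were seen. Those draws listed 7636 abemaciclib and 10866 combination regions, where 17860 and 19273 were seen. With lists so unlike the real ones, they do not show what share of the gains depth explains. Draws with 1 factor per library gave 2863 gained and 2363 lost regions. These draws, too, listed fewer regions than were seen, 15907 under abemaciclib and 16407 under the combination. The peaks gained and lost were mostly weak, and the weakest 20% of each list held 50.6% of the gained and 56.9% of the lost ones. Over the merged regions, 291 of the 3630 lost and 197 of the 5043 gained were listed under DMSO. All 8 of the strongest lost peaks were also listed under DMSO, as were all but 43 of the top 5000 abemaciclib peaks. They included chromosome 10 at 129923895 to 129924781 with 39 abemaciclib tags, 159 bp from a combination peak, chromosome 20 at 44441233 to 44441846 with 12.5-fold enrichment, chromosome 1 at 214776553 to 214777054 with 12.1-fold and chromosome 10 at 62537978 to 62538824 with 11.2-fold. None of the 16 strongest gained peaks was listed under DMSO. Examples were chromosome 1 at 169749978 to 169750535 with 10.1-fold enrichment, chromosome 9 at 75140464 to 75140921 with 37 summit tags and chromosome 10 at 109413946 to 109414402 with 13.1-fold. The largest losses in covered length were on chromosome 6 from 26200001 to 26300000, with 8 peaks against 14, on chromosome 2 from 11600001 to 11700000, with 1.76 kb against 4.03 kb, and on chromosome 21 from 43700001 to 43800000, with 1404 bp against 3601 bp. The largest gain was on chromosome 19 from 1100001 to 1200000, with 9 peaks against 3.

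At 12467 matched summits the combination had a median of 0.728 times the tags per depth of abemaciclib alone, with quartiles of 0.590 and 0.929, and was lower at 10036. This difference depended on the scale, since the median ratio of the authors' fold enrichment over local background was 0.998 at the same summits. That fold adds 1 tag to both summit and background, so it is itself not free of depth. Summits beyond their counting intervals around this median numbered 973 above and 824 below, where draws with 1 ratio for all gave 228 and 231 on average. Among summits with at least 100 tags over both libraries, the lowest ratio was on chromosome 2 at 10262399 to 10262734, with 21 against 96 tags, or 6.97-fold lower (4.32 to 11.8). Chromosome 17 at 79479486 to 79479838 was 4.26-fold lower (2.85 to 6.51) and chromosome 16 at 3030089 to 3030455 was 4.04-fold lower (2.64 to 6.31). Within the same set, the 5 highest ratios all lay on chromosome 20 between 50361249 and 52469433. The first of them, at 52389190 to 52390136, had 222 against 36 tags, or 4.04-fold (2.83 to 5.92), and the next, at 50449310 to 50449912, was 3.62-fold (2.15 to 6.48).

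**Figure D3:**
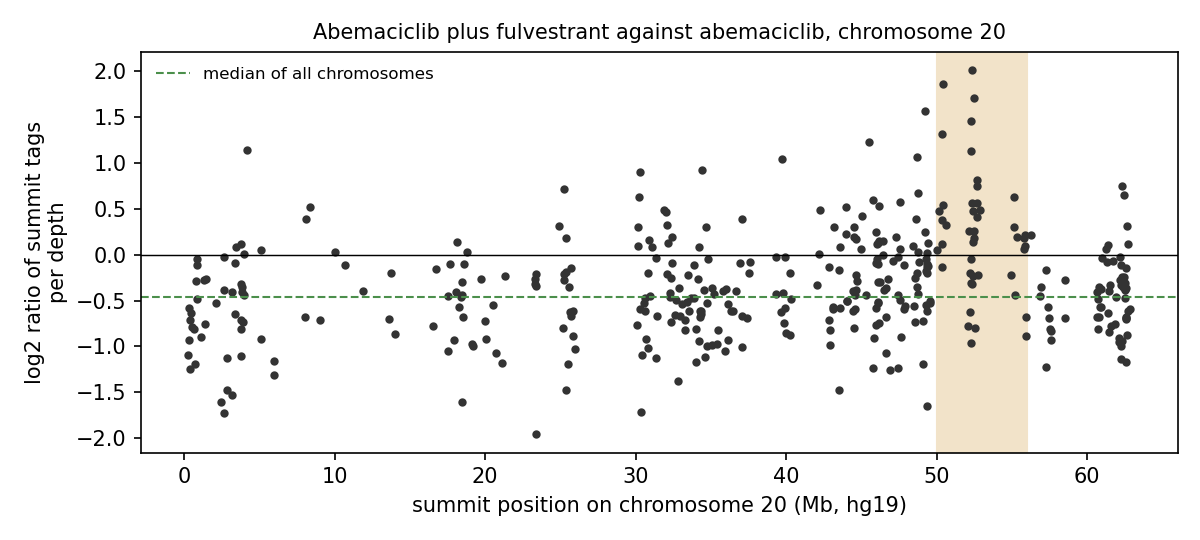
Points are matched peaks on chromosome 20, with the position of the summit in Mb on the x axis and the log2 ratio of summit tags per depth, combination against abemaciclib alone, on the y axis. Shading marks 50 to 56 Mb, where the median was 0.19 against -0.46 over all chromosomes (dashed line).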

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

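Of 111 alternative values for 24 results, thinning left aside, 74 stayed within 1.5 times the main value or, for median ratios, within the 95% interval of the median, 37 moved further and no ratio changed sign. More peaks were gained than lost in all 3 comparisons under each alternative run. At equal list lengths this surplus carries no direction, since it arises only where 1 peak overlaps several peaks of the other list. Equal list lengths moved most counts, and the change there follows from shorter treated lists. Against DMSO, abemaciclib then gained 2102 and lost 1555 peaks, the combination gained 2611 and lost 2021, and the combination against abemaciclib gained 1951 and lost 1844, with 11675 peaks left in each list, also for abemaciclib and the combination. The surplus of clusters in the treated lists also shrank there: clusters of at least 3 peaks without a peak of the other list were 4 against 4 for abemaciclib and DMSO, 10 against 6 for the combination and DMSO, and 6 against 0 for the combination and abemaciclib. A −log10 q of at least 10 left 6271, 10236 and 11222 peaks under DMSO, abemaciclib and the combination, with gained and lost peaks of 4177 and 141 for abemaciclib, 5276 and 240 for the combination, and 2254 and 1225 for the combination against abemaciclib. At a −log10 q of at least 5, the lost peaks were 366, 470 and 2273 in the same order of comparisons, and these counts follow from dropping weak peaks. The tests added after the data were seen were thinning to equal depth, leaving out regions of high background, the settings for matched summits, the fold enrichment in place of tags per depth, and clusters at equal list length. With fold enrichment, the median log2 ratio of abemaciclib to DMSO was 0.27 in place of 1.26, that of the combination to DMSO 0.25 in place of 0.76 and that of the combination to abemaciclib -0.0029 in place of -0.46. Tags in 10 kb gave 1.09, 0.66 and -0.37 in the same order, and the 2277, 2244 and 3122 peaks with most tags gave 1.28, 0.80 and -0.49. The cause was not tested. Thinning left 11191 of the 11675 DMSO peaks at a −log10 p of at least 3.65, the lowest in the abemaciclib list. A draw at the lowest deposited −log10 p listed too many DMSO regions, so thinning at such a threshold does not show what depth does. Draws at DMSO rates gave 7636 regions at the abemaciclib depth against 10918 at the DMSO depth. They covered merged regions at a threshold of 8.98, so this change cannot be compared with that under thinning. No paired analysis was possible because each treatment had 1 library, and for the same reason no library could be left out. Promoter, gene list and motif alternatives were not run, since no hg19 annotation or sequence was used here. Depth limits the weak peaks, whose summits rest on a median of 11 tags among those gained under abemaciclib.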

Other observations

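The tests of explanations in this part and the comparison of tags at matched summits were chosen after the results had been seen, while the counts of peaks per list were planned. The simulation with 1 factor per library was recalibrated once, after its first draw had listed too many DMSO regions.

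Chromosomes 17 and 20, on which MCF7 is known to carry amplified DNA, held the peaks with the most surrounding tags. The DMSO peak with the highest background, on chromosome 20 at 52208933 to 52211461, had 2814 tags in 10 kb, or 31.6 times the median of its list. Under abemaciclib the leader was chromosome 20 at 49347231 to 49347541 with 4895 tags, and under the combination chromosome 17 at 57921065 to 57921351 with 4285. Fold enrichment at these 3 peaks was 6.28, 1.74 and 1.85, with 479, 226 and 208 tags at the summits. Both treated lists began on chromosome 1 at positions 9771 and 9971, at the very end of the chromosome, with 9 and 12 summit tags, so no filter on such sequence had been applied there. In the strongest 1982 of 7926 regions listed in all 3 libraries, relative heights differed by similar amounts at each step. The spread beyond counting error, with intervals from resampled regions, was 0.25 (0.23 to 0.27) log2 units between abemaciclib and DMSO. Between the combination and abemaciclib it was 0.27 (0.25 to 0.29). Over all matched summits of each pair the spreads were less alike, 0.24 at 9089 summits and 0.35 at 12467.

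More peaks were listed in both treated libraries than under DMSO, and the tables argue against depth and counting error as the reason. The abemaciclib library held 0.652 times the depth of the DMSO library, and 99.1% of matched summits had more tags per depth under abemaciclib. Whether a single factor per library accounts for the pattern stayed undecided. Drawing it gave 5825 of the 7558 gained regions under abemaciclib, or 77.1%, between the deciding bounds of 50 and 80%. For the combination the same draw gave 6211 of 9065, or 68.5%, and it gave more lost regions under abemaciclib than were seen, 840 against 579. The draw cannot settle the question. Its rates at gained regions came from the treated libraries alone, and its threshold of 8.98 lay above the lowest listed −log10 p, 3.65 to 3.88. The size of the factor depends on the scale, 2.39-fold in tags per depth and 1.205-fold in the authors' enrichment over local background. The latter adds 1 tag to both summit and background and is not free of depth. More acetylation in the cells and a lower ChIP yield in the DMSO library cannot be told apart, because no reference chromatin set the scale and each treatment had 1 library.

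Relative peak heights spread more widely for the combination against DMSO than for abemaciclib against DMSO. The spread beyond counting error was 0.38 (0.36 to 0.41, from resampled regions) against 0.25 log2 units. Shifted summits alone would have left no gap with tags in 10 kb, where the ratio of the excess spreads was 1.33. At the summits that ratio was 1.51, so a partial contribution of shifted summits stays open. Without regions of over 10 times the median tags in 10 kb, the ratio was 1.51. That filter left 7850 of the 7926 regions, so amplified DNA below its cutoff was not tested and stays open. A response of particular regions to fulvestrant is a candidate explanation, and variation between single libraries, including the kit and the sonicator, stays open as well.

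On chromosome 20 between 50 and 56 Mb, matched peaks were higher in the combination library relative to abemaciclib alone, by 0.65 log2 units above the median of all regions, with 39 of 45 peaks above it. Relative to DMSO, 25 peaks of the combination and 26 of abemaciclib were matched. For the combination, their median at the summits was 0.89 (0.70 to 1.53, from resampled peaks) against a general level of 0.76. For abemaciclib it was 1.095 (0.62 to 1.43) against 1.26. Tags in 10 kb at these peaks gave shifts of -0.01 and -0.30 from the general level in the same order. Matching leaves out regions not listed under DMSO. Among those left out were the combination peaks from 52389190, 52308414 and 50449310, which were high in the ranking between the treated libraries. The ranked peak from 50361249 was kept. The matched peaks therefore cannot show whether the segment as a whole sat at the general level relative to DMSO. A difference in DNA copy number between the cultures cannot be told apart from changes at single regions. Between the treated libraries, tags in 10 kb shifted by 0.964 times the shift at the summits, but those tags include the peaks themselves. The peaks spread 1.51 times as widely as regions with as many tags. Against DMSO their spread was wider still, 1.82 times for abemaciclib and 1.69 times for the combination. The spread therefore does not bear on a shift shared by all of them. The segment was picked because its peaks led the ranking, and it held 43 DMSO, 73 abemaciclib and 90 combination peaks.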
